A study of Mus musculus with 20 samples.

How the data were processed

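The series holds 20 samples of mouse embryonic fibroblasts, 12 immunoprecipitated and 8 input. Per the labels' protocols, cells for the H3K27me3, CAP-D3 and CAP-H2 libraries were fixed with EGS, a long-arm protein crosslinker, followed by formaldehyde, and cells for TFIIIC with formaldehyde alone. Overlaps between TFIIIC and the other antibodies therefore join differently fixed chromatin.

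The deposited files are peak lists, 1 per immunoprecipitated library, so peaks were called per library and not on pooled replicates. Reads were aligned to mm9 with Bowtie2 2.3.0 and peaks called with MACS 1.4.0rc2, per the submitters' processing notes, which give neither the settings nor the order of these steps. Each line gives a position and the authors' score for the peak, deposited without a column name; this program writes a negative log10 of a p-value, times 10, there. The smallest score in a list was 50 to 50.4, and many peaks are tied at 3100. A score depends on read depth and on the input used, so it served to rank or filter peaks within a list; median scores and counts above a fixed score are given for both genotypes as a description, not as a measure of enrichment between them. Per the labels, the WT condensin II libraries share an input with H3K27me3 WT replicate 2, and the RbL ones with H3K27me3 RbL replicate 1. The number of reads is not given in the sources used here. A library with more reads tends to give more, wider and higher-scoring peaks, which limits every comparison of peak numbers between genotypes.

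Groups were taken from the sample labels. Peak number and covered length were compared on the log2 scale with two-sided exact permutation tests. Peaks of the 4 libraries of an antibody were merged where they overlapped, and regions were classed by the libraries with a peak. For the single condensin II libraries, shares are given with exact (Clopper-Pearson) 95% binomial intervals and no test across genotypes; the interval of the log2 ratio of peak numbers assumes Poisson counting. Expected overlaps came from 1000 circular shifts of 1 list along each chromosome (100 for pairs outside the condensin II comparisons and for fixed regions), which keep peak widths and spacing but not the mappability or openness of chromatin. One-sided permutation p-values were adjusted by Benjamini-Hochberg over 18 pairs of lists.

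Peaks were also counted in 1 Mb windows by their midpoint. The log2 share per 1000 peaks, with a pseudocount of 0.5 peaks, was compared between genotypes with limma (moderated variance with a trend) in windows with a mean of at least 5 peaks, with a Benjamini-Hochberg threshold of 0.05. Shares are relative to the total of a library, so a rise somewhere lowers the rest. The window test was tested on simulated peaks with the window means, library totals and median replicate spread of these data and 200 changed windows, with rises and falls balanced. For TFIIIC it recovered 52.0% of windows changed 1.5-fold and 89.0% of those changed 2-fold, with 7 and 4 false calls; for H3K27me3 it recovered 0, 15.5% and 52.5% at 1.5-fold, 2-fold and 3-fold. Every simulated window had the same replicate spread, whereas real windows may differ in theirs, so the recovery in the real data may be lower. A real TFIIIC window with a log2 difference of 0.74, chromosome 8 from 15000001 to 16000000, had a limma adjusted p of 0.349. Windows that were not called may therefore still have changed. An earlier simulation whose changes altered the library totals gave more false calls and was replaced. The overlap ratio was tested by planting CAP-H2 peaks at 25% and 50% of CAP-D3 peaks, which gave ratios of 8.67 and 16.4, and 0.985 with none planted.

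The main tests and most alternatives were fixed before the data were examined, but several tests of explanations were chosen later. Regions named in the text were also chosen by a rule fixed before the data were examined. For H3K27me3 and TFIIIC these are the 12 regions per direction with the highest minimum score over the 2 libraries of the genotype that has them; for CAP-D3 and CAP-H2, the 12 highest-scoring peaks per genotype with none of the other within 1 kb; the 5 highest-scoring regions found in every library of an antibody; and the 5 windows per direction with the smallest p. Only the leading ones are named. Ties at the score of 3100 were broken by mean score and then width, a choice made after the scores were seen. Unplaced sequences were left out of windows, overlaps, region classes at condensin II and named regions, but count in peak numbers, covered length and numbers of merged regions. Coordinates are 1-based.

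The alternatives were a score of at least 100; leaving out each replicate; leaving out 89 regions with a peak in all 12 lists; equal numbers of top-scoring peaks; other overlap rules (a gap of up to 1 kb, or at least 50% of a peak); uniform random placement; windows of 500 kb with a mean of at least 2.5 peaks; a pseudocount of 2 peaks; no window filter; covered length in place of peak number; and the replicate number as a block. Added after seeing the data were a score of at least 500, leaving out chromosome X, equal peak numbers in the condensin II overlaps, fixed condensin II regions, the classes of regions at condensin II, the recovery of TFIIIC regions by score class and, in each RbL library, at matched WT score (20 classes), and a crossed block. Promoter shares, divergent promoter pairs and 15 gene lists were planned, but not run, because they need a gene annotation of mm9, which was not used here.

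Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.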

Results

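Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in mouse embryonic fibroblasts, primary cells grown out of C57BL/6 embryos and used at low passage while cycling. Wild-type cells (WT) were compared with cells homozygous for the L allele of Rb1 (RbL), which changes the LXCXE-binding cleft of the retinoblastoma protein pRb. Each of 4 antibodies was used in both genotypes: against CAP-D3 and CAP-H2, both subunits of the condensin II complex, against TFIIIC, a DNA-binding factor of RNA polymerase III genes, and against H3K27me3, the histone mark set by Polycomb repressive complexes. H3K27me3 and TFIIIC had 2 libraries per genotype, and CAP-D3 and CAP-H2 had 1. The 12 peak lists were analysed; the 8 input samples have no list of their own here. By the series title, the study concerns the recruitment of condensin II to promoters by pRb. Gene and promoter assignments were not made, as no annotation of the mm9 genome build was used here, so regions are given by mm9 position alone. The number of reads behind each list is unknown, and the labels do not say whether libraries with the same label came from separate cultures, so that p-values between genotypes measure the spread between these libraries, which may be technical. Permutation p-values of overlaps measure the placement of peaks within a pair of lists instead.

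Most of the strongest CAP-D3 sites were called in both genotypes, while the weaker ones often were not. The WT list held 17576 CAP-D3 peaks and the RbL list 13233, a log2 ratio of −0.41 (95% interval −0.44 to −0.38). Among WT peaks, 53.4% (95% exact binomial interval 52.7 to 54.2) were overlapped by an RbL peak, where circular shifts of the WT peaks gave 0.91%. With the WT list cut into 4 equal classes by score, that share was 99.7%, 72.3%, 23.4% and 18.4% from the highest to the lowest class. In the other direction, 70.2% of RbL peaks were overlapped by a WT peak. No RbL peak lay within 1 kb of 7711 WT peaks (43.9%), and no WT peak within 1 kb of 3631 RbL peaks (27.4%). At a score of at least 500 the RbL list was the longer one, with 8462 peaks against 7218 (log2 ratio 0.23), and the median score was 358 in WT and 740 in RbL; scores of lists with different inputs and unknown read depth do not measure enrichment between genotypes. With 1 library per genotype there is no replicate check, and these intervals, like all binomial intervals here, cover counting error only.

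CAP-H2 was called at a similar number of places in the 2 genotypes, 42737 in WT and 43151 in RbL (log2 ratio 0.01, 95% interval −0.01 to 0.03). An RbL peak overlapped 71.1% of the WT peaks (95% interval 70.7 to 71.6), against 3.55% after circular shifts. By score class of the WT list, the shares were 98.9%, 85.0%, 57.0% and 43.5%. Peaks with none of the other genotype within 1 kb numbered 10243 in WT and 10198 in RbL, with median scores of 84.2 and 115. At a score of at least 100, the lists held 27741 WT and 34697 RbL peaks (log2 ratio 0.32), and at a score of at least 500, 5585 and 8738 (log2 ratio 0.65).

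The highest-scoring CAP-D3 peak of WT cells without an RbL peak within 1 kb lay on chromosome 16 from 87611576 to 87612321, with a score of 2172. It was followed by peaks on chromosome 14 from 8712627 to 8713539 (score 1801) and on chromosome 8 from 126755050 to 126755957 (score 1718), both of which had a CAP-H2 peak in both genotypes. Of the 12 highest-scoring WT peaks of this kind, 7 had a CAP-H2 peak in both genotypes. In RbL cells, the corresponding CAP-D3 peaks were led by chromosome 6 from 125826790 to 125827368 (score 3213) and chromosome 18 from 45215541 to 45215925 (score 2290), neither with a CAP-H2 peak. Of the 12 RbL peaks, 5 had a CAP-H2 peak in both genotypes. For CAP-H2, the RbL list had a peak with the score of 3100 on chromosome 5 from 4052256 to 4054613 and one of 2850 on chromosome 11 from 88828917 to 88832366, the latter together with a CAP-D3 peak called in RbL and not in WT. The highest-scoring CAP-H2 peak without an RbL partner, on chromosome 1 from 36752671 to 36754686, had a score of 988 and a TFIIIC peak in all 4 TFIIIC libraries. All 5 of the strongest CAP-H2 regions of both genotypes, among them chromosome 16 from 45740401 to 45745166 and chromosome 2 from 30295481 to 30298177, also had a CAP-D3 peak in both.

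CAP-D3 peaks overlapped CAP-H2 peaks far above chance in each genotype, although most CAP-H2 peaks had no CAP-D3 peak. In WT, 9701 of the 17576 CAP-D3 peaks (55.2%) overlapped a CAP-H2 peak, against 3.13% expected from circular shifts, a ratio of 17.6. In RbL it was 8653 of 13233 (65.4%) against 3.34%, a ratio of 19.6. Both permutation p-values were 0.001, the smallest that 1000 shifts can give (0.0018 after Benjamini-Hochberg adjustment over the 18 pairs of libraries tested). CAP-D3 peaks shared between genotypes carried the other subunit more often than the rest: in WT, 70.5% of those with an RbL peak within 1 kb overlapped a WT CAP-H2 peak (95% interval 69.5 to 71.4), and 35.7% of the others did (34.6 to 36.7). In RbL, these shares were 72.5% (71.6 to 73.4) and 46.7% (45.0 to 48.3). Peak strength moved with this class, as the median score was 946 for shared and 233 for other peaks in WT, and 1238 and 388 in RbL. Seen from CAP-H2, 26.0% of WT peaks with an RbL peak within 1 kb overlapped a WT CAP-D3 peak, and 8.10% of the others did. In RbL, these shares were 23.1% and 8.96%. The 2 subunits of a genotype share an input and a fixation, which circular shifts do not account for. Merging the lists gave 9144 CAP-D3 regions and 29067 CAP-H2 regions with a peak in both genotypes, and 5852 regions with a peak of both subunits in both.

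Condensin II peaks coincided with TFIIIC peaks in WT cells, and hardly beyond chance in RbL cells. In WT, 5020 and 4746 of 17576 CAP-D3 peaks overlapped a peak of TFIIIC libraries 1 and 2, a mean of 27.8 ± 1.10% (SD, n = 2) where shifts gave 13.1 ± 1.84% (ratios 2.42 and 1.87, both with a permutation p of 0.001 and an adjusted p of 0.0018). In RbL, 21.3% and 20.9% did so, where shifts gave 20.2% and 20.5% (ratios 1.05 and 1.02, adjusted permutation p 0.0817 and 0.3394). CAP-H2 gave ratios of 1.77 and 1.51 in WT (adjusted permutation p 0.0018 each) and of 1.06 and 1.05 in RbL (adjusted permutation p 0.0115 and 0.0195). The observed CAP-H2 shares differed little, at 24.0% and 24.5% in WT and 22.1% and 22.2% in RbL, and most of the change in ratio came from the share expected, which was 14.9 ± 1.92% in WT and 21.0 ± 0.22% in RbL. For CAP-D3, both moved: the mean share expected rose from 13.1% in WT to 20.3% in RbL, and the mean observed fell from 27.8% to 21.1%. Over the 2 TFIIIC libraries per genotype, the mean ratio with CAP-D3 was 2.15 ± 0.39 in WT and 1.04 ± 0.02 in RbL (SD, n = 2), and with CAP-H2 it was 1.64 ± 0.19 and 1.06 ± 0.01. Both RbL libraries lay below both WT libraries, but the values of a genotype share a single condensin II list and are not independent, and no p-value was computed between genotypes. The RbL ratios with CAP-D3 went below 1 at a score of at least 100 (0.97 and 1.00) and when at least 50% of the CAP-D3 peak had to be covered (0.83 and 0.77). Those with CAP-H2 were 0.98 and 0.97 under the latter rule and 0.96 each at equal peak numbers, and that of library 1 was 1.02 at a score of at least 100, no longer past the threshold.

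**Figure D1:**
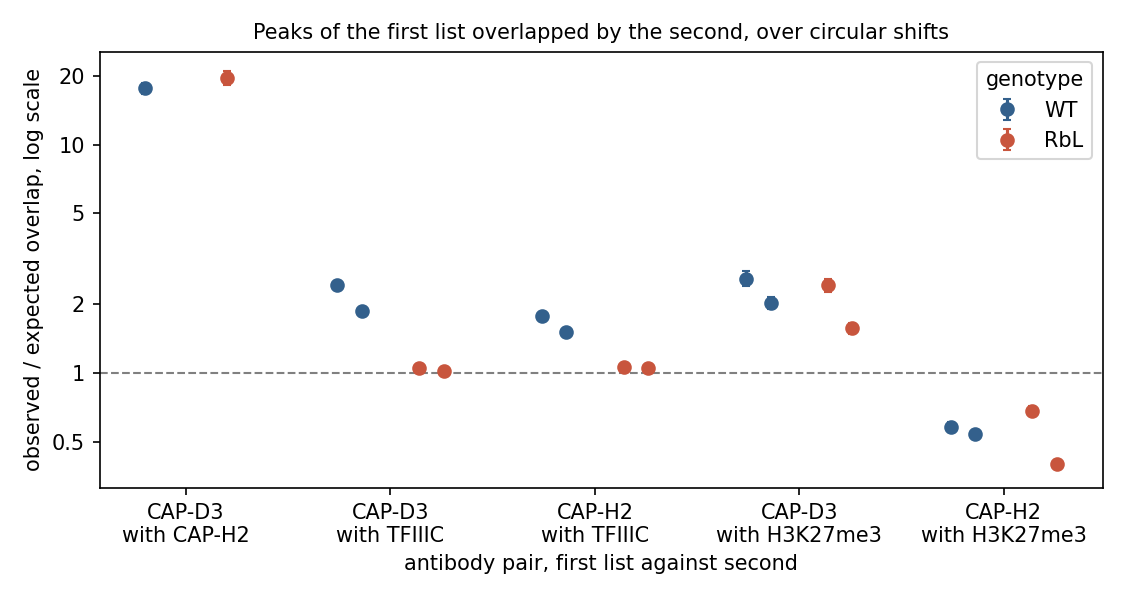
Ratio of observed to expected overlap (log axis) for each pair of peak lists within a genotype; each point is 1 pair of libraries, blue for WT and red for RbL, the bars are the SD of the ratio over 1000 circular shifts, and the dashed line marks a ratio of 1. TFIIIC sits at 1.51 to 2.42 in WT and at 1.02 to 1.06 in RbL, while CAP-D3 with CAP-H2 is at 17.6 and 19.6.

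The difference was also seen at condensin II regions held fixed across genotypes, where the observed share fell mainly at regions with CAP-D3 and little at CAP-H2 regions as a whole. Of the 9144 CAP-D3 regions found in both, 40.4% and 37.5% had a peak in the 2 WT TFIIIC libraries, and 25.0% and 24.7% in the 2 RbL libraries, although shifts gave less for WT (14.6% and 17.5%) than for RbL (22.4% and 22.8%). With the same number of 200350 top-scoring TFIIIC peaks taken from every library, the shares were 40.4% and 28.1% in WT and 15.2% and 14.8% in RbL, but this trims the longer RbL lists most and WT replicate 1 not at all. At the 5852 regions of both subunits, TFIIIC peaks were present at 53.5% and 49.3% in WT and at 35.3% and 34.4% in RbL, where shifts gave 19.6% and 22.7% in WT and 28.4% and 28.6% in RbL. The RbL ratios there were 1.24 and 1.20 (permutation p 0.01 each, the smallest that 100 shifts can give) and 1.07 and 1.04 at equal peak numbers (permutation p 0.079 and 0.168). Of the 29067 CAP-H2 regions found in both genotypes, 27.5% had a peak in each WT library and 24.2% in each RbL library, where shifts gave 15.7% and 18.6% in WT (ratios 1.75 and 1.48) and 23.6% and 23.9% in RbL (ratios 1.02 and 1.01). At equal peak numbers these shares were 27.5% and 20.9% in WT and 15.9% and 15.8% in RbL. Counted by peaks as deposited, the CAP-H2 difference was absent. WT CAP-H2 peaks with an RbL peak within 1 kb had a TFIIIC region of both WT libraries in 20.69% and of both RbL libraries in 20.65%. WT CAP-H2 peaks without one had them in 13.5% and 17.1%. CAP-H2 regions without CAP-D3 were not counted apart.

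TFIIIC regions that the RbL lists lacked lay at condensin II regions more often than other classes of TFIIIC regions did, although most of them lay elsewhere. Of the 7066 regions on placed chromosomes with a peak in both WT and no RbL library, 650 (9.20%, 95% interval 8.53 to 9.90) lay at a CAP-D3 region of both genotypes, and of the 41044 regions with a peak in both RbL and no WT library, 117 (0.29%, 0.24 to 0.34) did. Regions found in 1 WT and 1 RbL library gave 0.81% to 1.24%, and the 77521 regions of all 4 libraries 1.91%. At CAP-H2 regions of both genotypes, the shares were 13.5% for WT alone, 1.49% for RbL alone, 2.75% to 3.56% for 1 library of each genotype and 5.56% for all 4. The shares for WT alone depended on the libraries used: at CAP-D3 regions they were 3.35% without WT replicate 1, 4.22% without WT replicate 2, 6.53% without RbL replicate 1 and 6.12% without RbL replicate 2, and at CAP-H2 regions 6.45%, 7.70%, 10.4% and 10.04%.

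**Figure D2:**
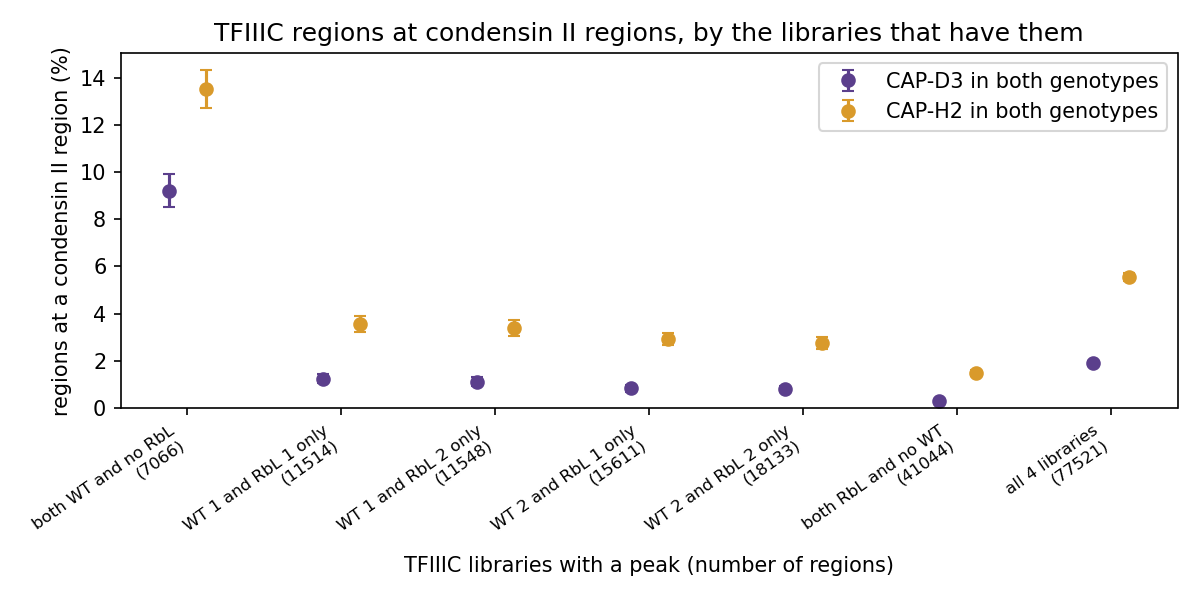
Share of TFIIIC regions (vertical axis, %) that lie at a CAP-D3 (purple) or CAP-H2 (yellow) region found in both genotypes, for regions grouped by the TFIIIC libraries that have a peak (horizontal axis, number of regions in brackets); points are shares and bars exact 95% binomial intervals, which cover counting error and not the choice of libraries. Regions of both WT libraries and no RbL library stand highest, at 9.20% and 13.5%, and those of both RbL libraries and no WT library lowest, at 0.29% and 1.49%.

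Recovery of WT TFIIIC regions counts the same overlap in another way and is not separate support. Of TFIIIC regions called in both WT libraries, 1482 of 2717 at CAP-D3 regions were also called in both RbL libraries (54.5%, 95% interval 52.7 to 56.4), against 76039 of 96958 elsewhere (78.4%, 78.2 to 78.7). Within 4 equal classes of the WT TFIIIC score, from highest to lowest, recovery was 83.4%, 51.5%, 41.7% and 30.2% at CAP-D3 regions and 95.4%, 81.0%, 72.5% and 64.9% elsewhere. At CAP-H2 regions it was 90.4%, 68.5%, 57.3% and 48.1%, against 95.4%, 81.0%, 72.6% and 65.2% elsewhere. In the opposite direction, TFIIIC regions of both RbL libraries were found in both WT libraries more often at CAP-D3 regions (1482 of 1950) than elsewhere (76039 of 186485, 40.8%). This counts the same 1482 and 76039 regions over other totals.

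**Figure D3:**
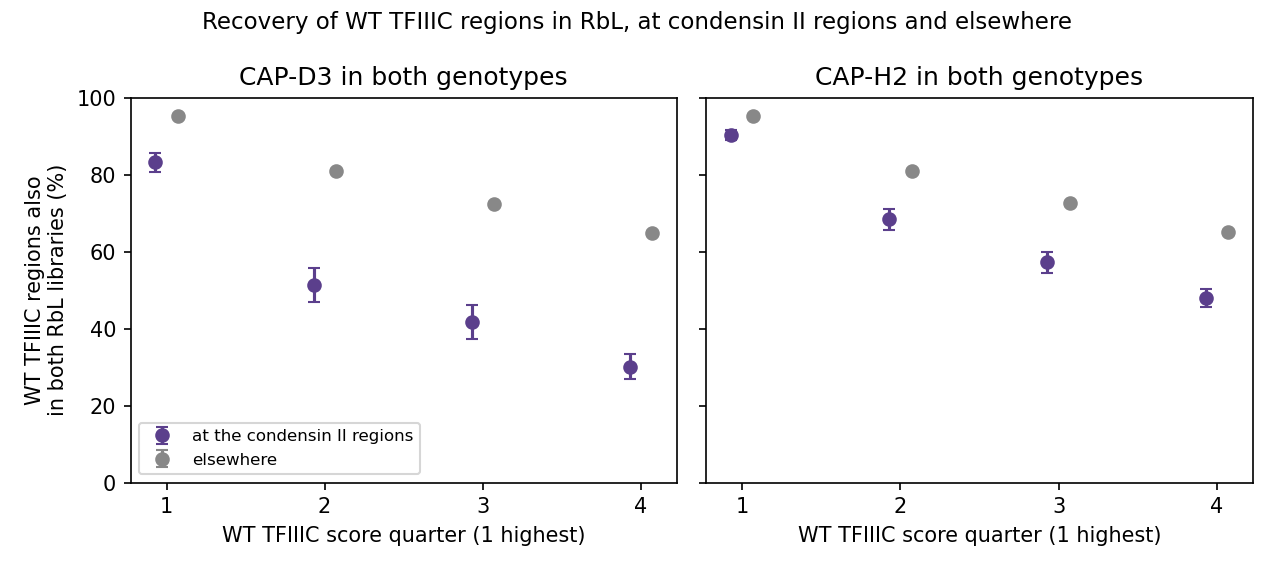
Share of TFIIIC regions of both WT libraries that were also called in both RbL libraries (vertical axis, %), by class of the WT score (horizontal axis, 1 highest), at regions with CAP-D3 (left) or CAP-H2 (right) in both genotypes (purple) and elsewhere (grey); bars are exact 95% binomial intervals. Recovery is lower at the condensin II regions in each class, 30.2% against 64.9% for CAP-D3 in the lowest.

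Of the 12 strongest TFIIIC regions of WT cells with no RbL peak, 7 had a condensin II peak, and 4 of these had both subunits in both genotypes: chromosome 17 from 34066067 to 34067974, chromosome 5 from 138611823 to 138613291, chromosome 19 from 41922026 to 41923237 and chromosome 8 from 119444892 to 119446123. Their lower TFIIIC score of the 2 WT libraries was 683, 629, 603 and 569. The top region, chromosome 12 from 109513006 to 109514356 (scores 1276 and 802), carried H3K27me3 in all 4 libraries and both condensin II subunits in RbL but not in WT. None of the 12 strongest TFIIIC regions of RbL cells with no WT peak had a condensin II peak. They were led by chromosome 17 from 25870339 to 25873673 (scores 1666 and 1807) and chromosome 4 from 130673212 to 130675525 (scores 1597 and 1782).

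TFIIIC peak calls covered more of the genome in RbL than in WT libraries. No control immunoprecipitation was analysed, so how many of these calls are sites of TFIIIC binding is unknown, here and in the overlaps above. The lists held 220155 ± 28008.5 peaks in WT and 298004 ± 5472.3 in RbL (SD, n = 2), a log2 ratio of 0.44, and covered 173 ± 29.7 Mb and 273 ± 4.51 Mb, a log2 ratio of 0.67. Mean peak width was 781 ± 35.6 bp in WT and 916 ± 1.69 bp in RbL. Both RbL libraries exceeded both WT libraries in number and in covered length, with a two-sided exact permutation p of 0.333 for each, the smallest that the design allows. Of 438722 merged regions, 77888 had a peak in all 4 libraries, 41113 in both RbL and no WT library, and 7078 in both WT and no RbL library, while the 4 pairings of 1 WT with 1 RbL library gave 11560 to 18162. With 200350 top-scoring peaks from each library, the numbers were 20511 for RbL alone, 12210 for WT alone and 10937 to 13863 for the mixed pairings.

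No 1 Mb window changed its share of TFIIIC peaks at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 2582 windows, 257 at an unadjusted p under 0.05). Parted by replicate number instead of genotype, the same libraries gave 199 at an unadjusted p under 0.05 and 1 called window (limma). With WT replicate 1 and RbL replicate 2 against the other 2 libraries, it was 9 at an unadjusted p under 0.05 and 0 called (limma). The smallest p-values belonged to peak-dense windows with a lower share in RbL, chromosome 5 from 125000001 to 126000000 (1.54 and 1.49 per 1000 peaks in WT, 1.10 and 1.12 in RbL, log2 difference −0.45 ± 0.05 SE, limma adjusted p 0.207), chromosome 10 from 79000001 to 80000000 (−0.46 ± 0.06, limma adjusted p 0.207) and chromosome 17 from 56000001 to 57000000 (−0.41 ± 0.05, limma adjusted p 0.207). Of windows with a higher share in RbL, chromosome 2 from 178000001 to 179000000 had the smallest p (0.65 and 0.70 per 1000 peaks in WT, 0.91 and 0.94 in RbL, log2 difference 0.45 ± 0.07, limma adjusted p 0.314). Leaving out chromosome X brought 4 windows under the threshold, all lower in RbL: the 3 just named and chromosome 10 from 80000001 to 81000000. Leaving out WT replicate 2 brought 249, of which 166 were higher and 83 lower in RbL, 71 of them on chromosome X.

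**Figure D4:**
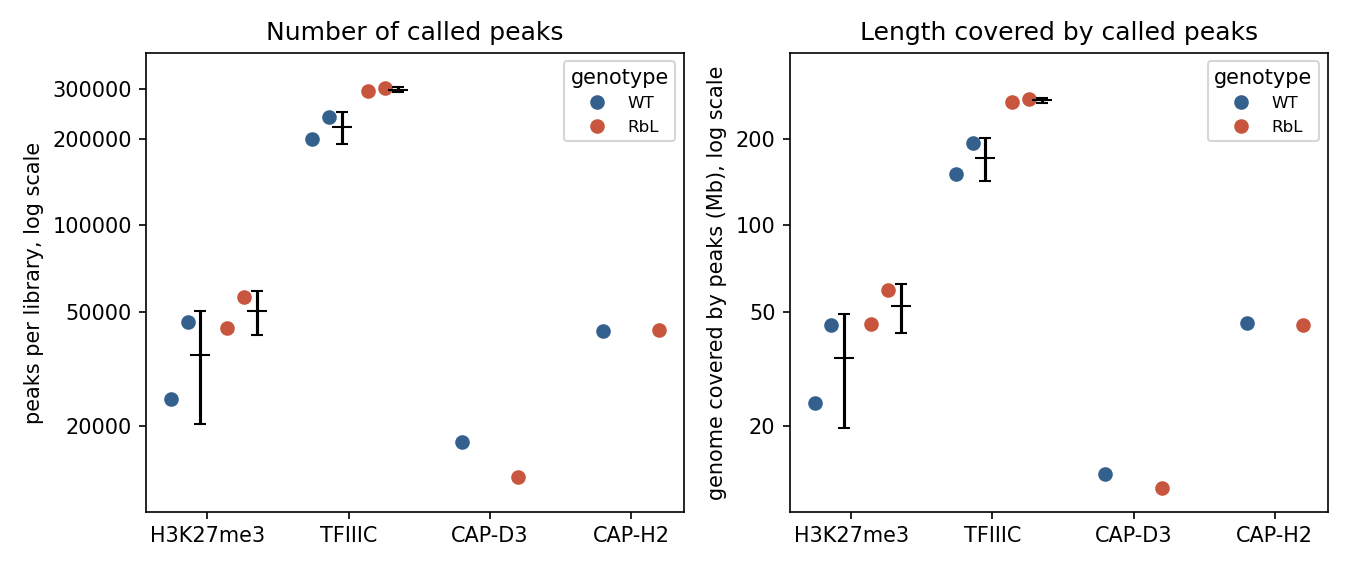
Number of called peaks (left) and genome length they cover in Mb (right), both on log axes, for the 4 antibodies; points are libraries, blue for WT and red for RbL, and black bars the mean ± SD of the 2 libraries where there are 2. TFIIIC covers 152 and 194 Mb in WT and 270 and 276 Mb in RbL, whereas the H3K27me3 libraries of the 2 genotypes overlap in peak number.

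H3K27me3 peaks numbered 35360 ± 15017.5 in WT and 50173.5 ± 8799.9 in RbL (SD, n = 2; log2 ratio 0.56, two-sided exact permutation p 0.667), and RbL replicate 1 had fewer than WT replicate 2. The order of these 2 libraries turned at a score of at least 100 (43406 against 43299) and without chromosome X, with an exact permutation p of 0.333 each. They covered 34.3 ± 14.7 Mb and 52.2 ± 10.0 Mb (log2 ratio 0.66, exact permutation p 0.333). Broad peaks of over 5 kb made up 1.24% and 1.36% of the WT lists and 1.75% and 1.87% of the RbL lists. Of 89389 merged regions, 7497 were found in all 4 libraries and 60684 in only 1. Both RbL and no WT library shared 4632 regions, and both WT and no RbL library 658, but WT replicate 2 and RbL replicate 2 alone shared 4501, so the RbL count hardly exceeded that of a mixed pairing.

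The H3K27me3 region of both RbL libraries with the highest score and no WT peak was on chromosome 1 from 135783126 to 135785664 (scores 937 and 1074), followed by chromosome 6 from 99901452 to 99903499 (900 and 852) and chromosome 9 from 106064949 to 106067130 (1226 and 768). None of the 12 regions of this kind had a condensin II peak. In WT, the corresponding regions were led by chromosome X from 50827126 to 50828600 (439 and 805) and chromosome 5 from 36134482 to 36136118 (430 and 524). Among the 5 named regions with H3K27me3 in all 4 libraries, which were tied at a lowest score of 3100, was chromosome 1 from 78165029 to 78218473, where the merged peaks of the 4 libraries spanned 53.4 kb.

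On chromosome X, WT replicate 2 differed from the other 3 H3K27me3 libraries. It had 3034 X peaks, 6.60% of its list (95% interval 6.37 to 6.83), against 0.43% in WT replicate 1, 0.77% in RbL replicate 1 and 1.36% in RbL replicate 2. No 1 Mb window passed an adjusted p of 0.05 for a changed share of H3K27me3 peaks (limma, 1557 windows, 46 at an unadjusted p under 0.05). The libraries parted by replicate number instead of genotype gave 177 windows at an unadjusted p under 0.05 and 0 called (limma). With WT replicate 1 and RbL replicate 2 against the other 2 libraries, it was 23 and 0 (limma). Single libraries decided the number of windows called between genotypes. Without WT replicate 1, 34 windows were called, all lower in RbL and all on chromosome X. Without WT replicate 2, 82 were called, 54 higher and 28 lower in RbL, 10 of them on chromosome X. Windows with the smallest p over all 4 libraries were chromosome X from 131000001 to 132000000, lower in RbL (log2 difference −1.66 ± 0.39 SE, limma adjusted p 0.972), and chromosome 15 from 6000001 to 7000000, higher in RbL (1.41 ± 0.38, limma adjusted p 0.972).

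**Figure D5:**
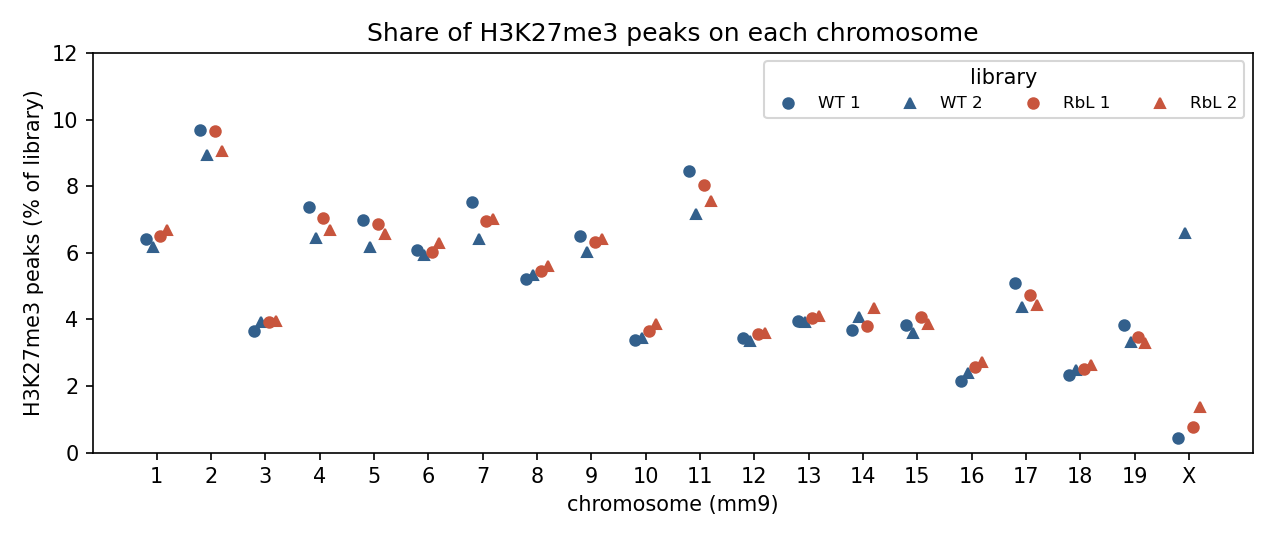
Share of H3K27me3 peaks (vertical axis, % of the peaks of a library on placed chromosomes) on each mm9 chromosome (horizontal axis; Y not drawn); each point is 1 library, blue for WT and red for RbL, circles for replicate 1 and triangles for replicate 2. On X, WT replicate 2 is at 6.60%, and the other 3 libraries are at 0.43% to 1.36%.

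Over all their peaks, the 2 condensin II subunits differed in their relation to H3K27me3. CAP-D3 peaks overlapped H3K27me3 peaks more often than shifted lists, at ratios of 2.59 and 2.03 for the 2 WT libraries and of 2.43 and 1.57 for the 2 RbL libraries (adjusted permutation p 0.0018 for each). CAP-H2 peaks overlapped them less often, at 0.58 and 0.54 in WT and 0.69 and 0.40 in RbL (permutation p for a lower overlap 0.001 each, the smallest possible). The genotypes overlapped in both cases. At the 5852 regions of both subunits the ratios were mixed, 1.23 and 0.98 in WT and 1.53 and 0.77 in RbL, and without regions that have a peak in all 12 lists they were 0.71 and 0.68 in WT and 1.24 and 0.54 in RbL. Among the 7497 H3K27me3 regions of all 4 libraries, 522 (6.96%, 95% interval 6.40 to 7.56) lay at a CAP-D3 region of both genotypes and 315 (4.20%, 3.76 to 4.68) at such a CAP-H2 region. CAP-D3 was less common at the 4632 H3K27me3 regions of RbL alone (0.65%) and at the 658 of WT alone (1.22%), which were narrower, with median widths of 1006.5 bp and 893 bp against 3183 bp.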

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

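The tests of TFIIIC peak number, of fixed condensin II regions and of recovery at CAP-H2 regions and at matched scores, and the score threshold for CAP-D3, were chosen after the results were seen; the tests of chromosome X and of recovery by score class at CAP-D3 regions were chosen once those patterns had been noticed, but before their own outcomes were known.

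TFIIIC lists contained peaks on sequences without a place in the assembly, which count in peak numbers, covered length and numbers of merged regions and were left out of overlaps, windows and named regions, whereas the H3K27me3, CAP-D3 and CAP-H2 lists had 0. WT replicate 1 had 2578 such peaks, of which 2093 were on Y_random (Y-derived sequence without a position). WT replicate 2 had 692, with 148 on Y_random. RbL replicate 1 had 1361, with 744 on Y_random, and RbL replicate 2 had 787, with 185 there. The share of TFIIIC peaks on chromosome X was 1.24%, 3.47%, 2.23% and 3.33% in the same order.

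The high chromosome X share of H3K27me3 peaks in WT replicate 2 was not a matter of peak number. Among the 24741 top-scoring peaks of each library it was 6.62% in WT replicate 2 and at most 1.44% in the others. It was not confined to a few loci either, as WT replicate 2 had the most peaks per 1000 in 83.1% of the 130 X windows with a peak, against 21.3% of the 2336 autosomal windows. This is in line with an X-wide mark in the cells of that library, such as an inactive X chromosome in cells of female embryos. The labels give no sex, so this was not tested. The condensin II lists of WT, which share an input with that library, had X shares close to those of RbL (2.13% and 2.14% for CAP-D3, 1.32% and 1.21% for CAP-H2). Whether condensin II peak shares would follow an H3K27me3 mark on X was not tested, so they do not decide the question.

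The lower share of CAP-D3 regions with a TFIIIC peak in RbL did not come from different CAP-D3 lists, as the highest RbL share at fixed regions was 25.0% against a lowest WT share of 37.5%. Equal peak numbers (highest RbL share 15.2%, lowest WT share 28.1%) decide nothing about peak calling, as they trim the longer RbL lists most. RbL libraries that were evenly weaker at every TFIIIC region would recover WT regions alike everywhere, but recovery was lower at CAP-D3 regions in every score class, by a median of −30.2 percentage points, and at matched WT scores by −20.5 and −22.3 points in RbL libraries 1 and 2. At CAP-H2 regions the median was −13.9, with −4.98 in the highest class, and at matched WT scores the differences were −9.72 and −10.6 points in the same order. The RbL TFIIIC lists were already the longer ones (294135 and 301874 peaks against 200350 and 239960 in WT), so rejecting evenly weaker RbL libraries adds little. Deeper calling alone would add peaks at the fixed CAP-D3 regions. The longer RbL lists, as deposited, instead had peaks at 25.0% and 24.7% of those regions, against 40.4% and 37.5% in WT. These values argue against deeper calling alone as the source of the lower CAP-D3 share. For the lower ratios to shifted lists, deeper calling in RbL stays open. Less specific calling in the RbL libraries was not tested by recovery and stays open. Genotype stays open as a cause, and so does a difference in chromatin preparation between WT and RbL cells, including unspecific enrichment at open chromatin in the WT libraries, as no control immunoprecipitation was analysed here.

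The smaller number of CAP-D3 peaks in RbL stays open between lower enrichment, read depth and input. At a score of at least 500 the log2 ratio was 0.23 in favour of RbL, but scores from 1 library per genotype with different inputs and unknown depth do not decide between them.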

How the results depend on the processing

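The score of at least 500, the analyses without chromosome X, equal peak numbers in the condensin II overlaps and the crossed block were chosen after seeing the data. Of 234 alternatives computed for 36 results, 165 were classed as unchanged. These kept the direction and side of the threshold, stayed within the spread or, for counts of regions and windows, stayed within a fixed fold of the main count. RbL exceeded WT in TFIIIC peak number (log2 0.31 to 0.57) and covered length (0.50 to 0.85) and in H3K27me3 peak number (0.11 to 1.01) and covered length (0.21 to 1.11) under each of 8 alternatives; these designs cannot pass the threshold. Ratios above 1 for CAP-D3 with CAP-H2 (17.6 to 33.0), for CAP-D3 and CAP-H2 with TFIIIC in WT (1.64 to 2.96 and 1.34 to 2.11) and for CAP-D3 with H3K27me3 (1.44 to 3.37), and below 1 for CAP-H2 with H3K27me3 (0.35 to 0.71), held throughout.

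Ratios with TFIIIC in RbL lay near 1 and several turned. For CAP-D3 (libraries 1 and 2) they were 0.971 and 0.996 at a score of at least 100, 0.826 and 0.769 with at least 50% of the peak overlapped, 0.887 and 0.850 at equal peak numbers, and 0.993 for library 2 without regions found in all lists; library 1 passed the threshold under uniform placement (1.054). For CAP-H2 they were 0.980 and 0.969 with at least 50% overlapped, 0.959 and 0.957 at equal peak numbers, and 1.02 for library 1, no longer past the threshold, at a score of at least 100. For CAP-D3, the unadjusted permutation p for a lower overlap was 0.001 in each library with at least 50% overlapped and at equal peak numbers. The cause was not tested.

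Counts of regions moved by construction when a library was left out: for H3K27me3, 5845 to 29224 in RbL alone and 1114 to 17587 in WT alone; for TFIIIC, 64094 to 94076 and 14482 to 41689. Equal peak numbers gave 1760 (H3K27me3, RbL alone), 20511 and 12210 (TFIIIC, RbL and WT alone); gaps of up to 1 kb gave 3072 and 407 for H3K27me3 and 22442 and 4460 for TFIIIC; at least 50% overlap gave 1038 for H3K27me3 in WT alone. The share of WT CAP-D3 peaks overlapped in RbL was 65.0% at equal numbers, 56.1% within 1 kb and 51.5% with at least 50% overlapped; for CAP-H2, 79.0% at a score of at least 100, 76.0% within 1 kb and 67.2% with at least 50%. The log2 ratio of CAP-D3 peak numbers turned to 0.23 at a score of at least 500; that of CAP-H2 was 0.32 at 100 and 0.65 at 500. The share of TFIIIC regions of WT alone at CAP-D3 regions was 3.35% to 6.53% without 1 library and 6.65% at equal peak numbers, and that of RbL alone 0.161% to 0.404%. Windows called ranged from 0 to 82 (H3K27me3) and 0 to 249 (TFIIIC) without 1 replicate, where the lone sample is assumed to vary like the other group, and 4 TFIIIC windows were called without chromosome X.

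With the replicate number as a block, 0 windows were called for both antibodies (limma, 84 and 330 at an unadjusted p under 0.05), and 0 with crossed numbers. Deviations of same-numbered libraries correlated at 0.40 (H3K27me3) and 0.69 (TFIIIC), but at 0.29 for each without X and Y. The labels give these libraries only a number in common, and 2 pairs are too few to tell whether they share more. Promoter, divergent-promoter and gene-list results and their alternatives were not run. Read depth, which is unknown, limits every comparison of peak numbers.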

Other observations

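H3K27me3 and TFIIIC peaks coincided slightly more often in RbL than in WT. Over the 4 pairs of libraries within WT, the ratio of observed to shifted overlap was 0.93, 1.10, 0.90 and 1.03, and over the 4 pairs within RbL it was 1.20, 1.27, 1.17 and 1.22. The share of H3K27me3 peaks with a TFIIIC peak was 11.3% to 17.6% in WT and at least 24.3% in RbL, while shifts gave 12.6% to 16.1% and 20.9% to 21.2%. Pairs share libraries, so they are not independent, and the difference was not tested.

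CAP-D3 peaks of WT cells with an RbL peak within 1 kb had a TFIIIC region of both WT libraries in 28.5% and of both RbL libraries in 19.7%. WT CAP-D3 peaks without one had them in 12.2% and 12.5%, with little difference. For WT CAP-H2 peaks with an RbL peak within 1 kb the shares were 20.7% and 20.6%, and without one 13.5% and 17.1%.

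Grouping autosomal 1 Mb windows into 10 classes by their WT share of TFIIIC peaks gave no steady trend. In the densest class (259 windows) 63.7% had a lower share in RbL, but so had 65.9% in the second sparsest, while in the class below the densest it was 44.2%.

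The 5 strongest TFIIIC regions of all 4 libraries included wide blocks on chromosome 3 from 93005637 to 93024022 and chromosome 8 from 19914370 to 19932716, of 18.4 and 18.3 kb, with no condensin II or H3K27me3 peak in any list, and a region on chromosome 9 from 56070216 to 56072113 with a peak in all 12 lists.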
